A study of Trichoderma reesei with 9 samples.

How the data were processed

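The starting point was the gene count table deposited by the authors, with 9 columns of whole-number counts, 1 per library, for 10348 genes. The deposited FPKM table was used only for an alternative fit. Its values are the deposited counts divided by gene length and by a median-ratio size factor times the geometric mean of the totals, so the deposited FPKM table is not independent of the counts. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3. The genome build and annotation are not given in the sources used here. Of the gene identifiers in the deposited table, 9120 are NCBI identifiers, of which 9116 were found in a reference table of the QM6a v2.0 assembly, and 1228 are further gene models with their own numbers. Coordinates in the text are those of the deposited table. Per the labels, poly-A RNA was made into libraries and no strand-marking step is named, so counts of overlapping, antisense or near-identical genes are uncertain.

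Groups came from the strain in the labels, with 3 libraries each. The labels do not say whether the replicates were separate cultures, so each p measures only the spread between these samples, which may be technical. Library totals ran from 12127372 to 13493219 counts and 9466 to 9722 genes were detected per library. The spread between replicates relative to counting noise, as chi-square per degree of freedom over pairs of libraries, was 13.1 to 32.3 in the wild type, 147 to 334 in Δvps13 and 28.6 to 56.2 in Δvps21.

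Genes were kept by edgeR filterByExpr (minimum count 10), which left 8906; 303 genes had 0 counts in all libraries. Counts were scaled by TMM and fitted by edgeR quasi-likelihood with 1 mean per group over all 9 libraries (6 residual degrees of freedom, common biological coefficient of variation 0.287), and p values were adjusted by Benjamini-Hochberg over all tested genes, with a gene called at 0.05. The comparisons were each deletion strain with the wild type and Δvps21 with Δvps13. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Whether a gene named as the target was lost was read from the counts, and genes were looked up by name and description.

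Gene lists were patterns matched to the deposited descriptions, written before the counts were examined: cellulases and cellulose-active proteins, beta-glucosidases, hemicellulases, chitin and beta-1,3-glucan enzymes, sugar transporters, endosome and vacuolar sorting, vacuolar proton pump, autophagy, ER entry folding and glycosylation, vesicle transport, proteases and peptidases, cytosolic ribosomal proteins, ribosome biogenesis, proteasome, heat shock proteins and chaperones, mitochondrial respiration, lipid metabolism and transfer, secondary metabolism and cytochrome P450, conidiation and hydrophobins, mating and sexual development, nitrogen and amino acid uptake, transcription factors, redox defence, iron uptake, ABC and drug transporters, cell cycle DNA replication and cytoskeleton, and glycolysis and citric acid cycle. The patterns also catch genes whose role differs from the list name: xyr1 is among the hemicellulases, a GH17 gene (TRIREDRAFT_39942) and a dehydrogenase gene (TRIREDRAFT_123946) are among the cellulases, and homocitrate and methylcitrate synthases are among the citric acid cycle genes. The chaperone gene bip1 is described only as a predicted protein and lies outside the ER list. The beta-glucosidase list also takes genes described only by their enzyme family, such as the GH3 gene TRIREDRAFT_79669. The description does not give the activity of that gene. Lists with 5 or more tested genes were tested with limma camera at a preset correlation of 0.01, and the alternatives were an estimated correlation and limma fry. The rule for naming genes, fixed beforehand, took in each comparison the largest called rises and falls whose replicates do not overlap between the groups, with a mean of 10 CPM or more in the higher group and an informative description. It added the 2 largest rises and falls regardless of description, the strongest called members of each list, the most abundant members of the cellulase, beta-glucosidase, hemicellulase and ER lists, and a set of known regulators and markers. Any gene picked otherwise is marked as picked after the data were seen.

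Alternatives tried were DESeq2, limma with a trend on log2(FPKM + 1) for genes with an FPKM of 1 or more in 3 libraries, fits of the 2 groups alone, median-ratio size factors, scaling by library totals only, no filter beyond a total above 0, a stricter filter of 10 CPM in 3 libraries, an absolute log2 of 1 or more besides the adjusted p, a replicate block, and leaving out each library. A limma voom fit with sample quality weights and tests of how Δvps13 replicate 3 differs were added after the data were seen. A refit without the 50 most abundant genes was set out beforehand as a test of the ribosomal protein list. It could not test the list because TMM scaling already removes such an effect. A comparison with all genes under library totals took its place, but it is no separate test either, because scaling moves all genes of a library alike. The overlap between the strains was compared with 20 simulations that shared the wild-type libraries. The steps were tested on simulated data with the dispersion of these counts, the same in every group and so without the wider spread of Δvps13. In the Δvps13 comparison 22% of genes with a true 2-fold change and 84% with a 4-fold change were recovered. False calls were 3 of 109 there, 7 of 115 in Δvps21 against the wild type and 17 of 260 in Δvps21 against Δvps13. Of 200 unchanged lists, 5 had p below 0.05 by camera. Genes were simulated independently of each other, so this does not cover lists whose members are correlated. The estimated correlation was 0.487 for the cellulases and 0.472 for the ribosomal protein genes. No reads were aligned, no library was left out of the reported fit, and sequence variants, splicing and transcript boundaries were not analysed here.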

Results

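Gene-level RNA-seq counts from mycelia of Trichoderma reesei, a filamentous fungus that secretes cellulases, were compared between the parent strain Rut-C30 and 2 deletion strains, Δvps13 and Δvps21. Rut-C30 is called wild type here as in the labels, although it is itself a cellulase-hyperproducing mutant strain. All mycelia came from Avicel (microcrystalline cellulose) induction medium at 96 h. The series was made to record how the transcriptome differs when either of these genes of vacuolar protein sorting is deleted. In yeast, Vps13 is a lipid transfer protein at contacts between membranes, and Vps21 is an endosomal GTPase of the Rab5 family. Each group had 3 libraries, with totals of 13248683, 12830786 and 12399135 counts in the wild type, 12937525, 13493219 and 12127372 in Δvps13, and 13094496, 12726066 and 12574798 in Δvps21. The deposited table held 10348 genes, of which 8906 had enough counts to be tested. Because 7046 genes are described only as a predicted protein, gene lists built from descriptions cover a small part of the genome. Expression is given as CPM after TMM scaling, mean ± SD of 3 libraries. Changes are log2 ratios with their standard error (SE), and a gene was called at an adjusted p threshold of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg over all tested genes). Gene lists, the comparisons, the tests, the rule for naming genes and most alternative settings were chosen before the data were examined, and the few choices made later are marked as such.

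The wild-type and Δvps21 libraries formed tight groups, and the Δvps13 libraries did not. On the first principal component, which held 52.8% of the variance, the wild-type libraries lay at -47.5, -51.3 and -49.6 and the Δvps21 libraries at 59.2, 47.3 and 61. Replicates 1 and 2 of Δvps13 lay between them at 14.04 and 8.83, whereas replicate 3 lay beside the wild type at -42.1. On the second component (19.5%) Δvps13 replicate 1 stood apart at -66.67, with Δvps13 replicates 2 and 3 at -27.45 and 10.79. On the third component (14.06%) Δvps13 replicate 3 stood apart at -60.06, with the wild type at 21.2, 22.8 and 15.8. The mean correlation of Δvps13 replicate 3 was 0.945 with the wild-type libraries and 0.914 with the other Δvps13 libraries, that of Δvps13 replicate 2 was 0.941 and 0.948, and the wild-type libraries had 0.985 to 0.987 with each other. The median SD between libraries of a group, on the log2 CPM scale, was 0.191 in the wild type, 0.501 in Δvps13 and 0.228 in Δvps21. The 10 most abundant genes took 16.5, 19.1 and 23.5% of the counts in Δvps13 replicates 1, 2 and 3.

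**Figure D1:**
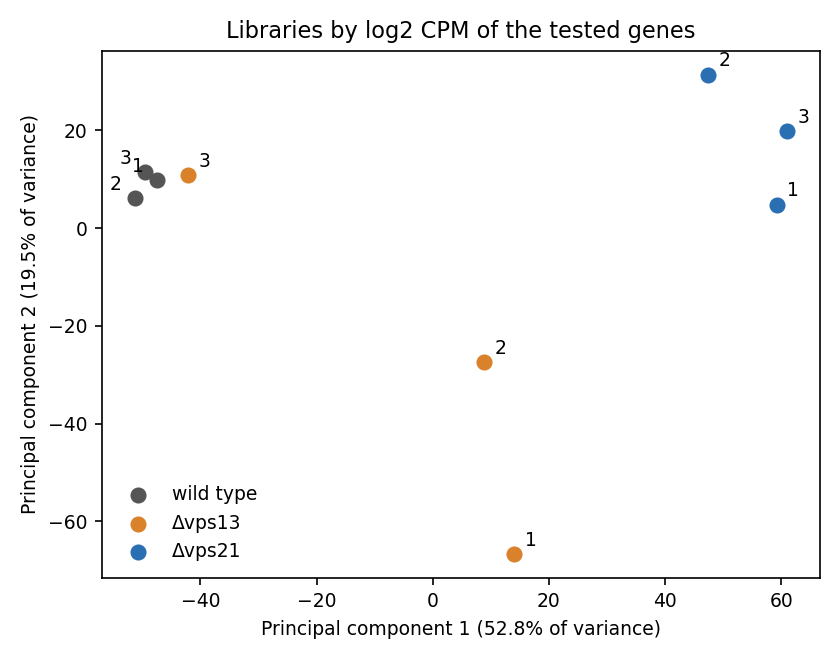
Principal components of log2 CPM over the tested genes, with axes labelled by their share of the variance; each point is 1 library, numbered by replicate and coloured by strain. Δvps13 replicate 3 lies at -42.1 on the first component, next to the wild type, and the Δvps21 libraries lie between 47.3 and 61.

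No gene in the deposited table carries vps13 or vps21 in its name or description, but 2 genes are described as rab5-like GTPases, the family to which Vps21 belongs. One of them, TRIREDRAFT_123015 (NW_006711164.1, 346840 to 347958), had 1607, 1365 and 1529 counts in the wild type and 1740, 1295 and 1147 in Δvps13. It had 2, 2 and 2 counts in the Δvps21 libraries. The summed counts were 4501 against 6, a ratio of 660.5 after scaling for library size (95% counting interval 303.2 to 1801), and the difference from the wild type was called (adjusted p = 1.81e-08). The other rab5-like gene, TRIREDRAFT_122593 (NW_006711160.1, 655116 to 656305), was expressed in all strains, at 145 ± 13.3 CPM in the wild type, 197 ± 39.6 in Δvps13 and 189 ± 4.01 in Δvps21. Its difference from the wild type was not called in Δvps13 (log2 0.44, adjusted p = 0.176, and 0.0441 without Δvps13 replicate 1) or in Δvps21 (log2 0.38, adjusted p = 0.171, and 0.0246 in a fit of the 2 groups alone). With sample quality weights (limma voom), a setting chosen after the data were seen, it was called in both (adjusted p = 0.0124 and 0.017). These weights were 0.187, 2.73 and 0.171 for Δvps13 replicates 1, 2 and 3. Every weighted Δvps13 mean thus rests mostly on replicate 2. The gene vps13 was not matched to an identifier, so its transcript was not followed in Δvps13. A search without names, made after the data were seen, covered genes with at least 10 CPM in every library outside the strain. In Δvps13, 0 genes stayed below 10% of every other library, against 3 in Δvps21. Loss of a target transcript was therefore not shown for Δvps13.

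The comparison of Δvps13 with the wild type asks which transcripts differ when vps13 is deleted. Several genes for enzymes that act on plant cell wall polymers rose. The glycoside hydrolase family 45 (GH45) gene TRIREDRAFT_49976 (NW_006711162.1, 200129 to 201106) rose 6.97-fold, from 458 ± 82.9 to 3194 ± 1037 CPM (n = 3 per group, log2 2.80, SE 0.32, adjusted p = 0.00139). The glucuronoyl esterase gene cip2 rose 6.62-fold, from 212 ± 47.4 to 1403 ± 644 CPM (log2 2.73, SE 0.37, adjusted p = 0.00268). The endoglucanase gene cel12a rose 5.09-fold, from 241 ± 72.9 to 1226 ± 341 CPM (log2 2.35, SE 0.32, adjusted p = 0.00268). The acetyl xylan esterase gene axe1 rose 9.10-fold, from 166 ± 29.7 to 1515 ± 1008 CPM (log2 3.19, SE 0.44, adjusted p = 0.00294; 5.75-fold without Δvps13 replicate 1), and the GH10 xylanase-family gene TRIREDRAFT_120229 rose 4.12-fold (log2 2.04, SE 0.26, adjusted p = 0.00245). In the early secretory pathway, the protein disulfide isomerase gene pdi1 rose 2.65-fold, from 326 ± 41.7 to 863 ± 92.2 CPM (log2 1.41, SE 0.23, adjusted p = 0.0065). The gene described as sec62, a protein of the endoplasmic reticulum (ER) entry pore (TRIREDRAFT_30455), rose 2.40-fold (log2 1.26, SE 0.17, adjusted p = 0.00274).

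Several transporters and enzymes outside wall degradation also rose in Δvps13. A lactate/pyruvate transporter gene, TRIREDRAFT_121441 (NW_006711154.1, 943843 to 945764), went from 31.2 ± 3.44 to 243 ± 111 CPM (log2 2.96, SE 0.31, adjusted p = 9.79e-04). A peptide transporter gene, TRIREDRAFT_124002, rose 6.88-fold, an NADP-dependent glutamate dehydrogenase gene, TRIREDRAFT_73536, 7.05-fold, a homeobox gene, TRIREDRAFT_121074, 7.91-fold (4.61-fold without Δvps13 replicate 1), and a malate dehydrogenase gene, TRIREDRAFT_119896, 3.19-fold (adjusted p = 0.00123, 0.00264, 0.00585 and 0.00451). TRIREDRAFT_119552, described only as a predicted protein, rose from 3.31 ± 1.36 to 224 ± 217 CPM (log2 6.07, SE 1.00, adjusted p = 0.00636; log2 5.10 without Δvps13 replicate 2). Another, TRIREDRAFT_112258, rose from 0.154 ± 0.141 to 13.7 ± 14.6 CPM (adjusted p = 0.00885, and 0.0589 without wild-type replicate 2). Among the decreases, min1 was 17.2-fold lower, at 5.43 ± 4.29 CPM against 90.9 ± 4.51 (log2 -4.11, SE 0.46, adjusted p = 0.00118; log2 -4.93 without Δvps13 replicate 3). TRIREDRAFT_109235, with a chitin-binding CBM18 module, was 12.6-fold lower (adjusted p = 3.12e-04), a manganese superoxide dismutase gene, TRIREDRAFT_66345, 6.55-fold lower (adjusted p = 9.79e-04), and a ferric reductase-like gene, TRIREDRAFT_111750, 5.07-fold lower (adjusted p = 0.00139). The pheromone receptor gene TRIREDRAFT_64018 was 4.99-fold lower and the hexokinase gene TRIREDRAFT_79677 was 3.55-fold lower (adjusted p = 0.00264 and 0.00268). Apart from TRIREDRAFT_112258, the genes named so far for this comparison kept their call when any 1 of the 9 libraries was left out.

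The most abundant cellulase transcripts were higher as well, but their calls depended on the set of libraries. The cellobiohydrolase gene cel7a (NW_006711176.1, 332378 to 334401) went from 10311 ± 1335 to 33956 ± 13110 CPM, 3.29-fold (log2 1.72, SE 0.42, adjusted p = 0.0264). Without wild-type replicates 1, 2 or 3 its adjusted p was 0.114, 0.139 or 0.0848, without Δvps21 replicates 2 or 3 it was 0.0548 or 0.0556, and in a fit of the 2 groups alone it was 0.118, and by limma on FPKM 0.0558. The GH6 gene TRIREDRAFT_72567 (NW_006711150.1, 12521 to 14440) went from 5693 ± 778 to 29968 ± 15230 CPM, 5.26-fold (log2 2.40, SE 0.46, adjusted p = 0.011, and 0.0543, 0.0773 or 0.052 without wild-type replicates 1, 2 or 3 and 0.0612 in the 2 groups alone). The ER Hsp70 chaperone gene bip1 rose 2.33-fold, from 561 ± 27.1 to 1307 ± 300 CPM (log2 1.22, SE 0.27, adjusted p = 0.019). Its adjusted p was 0.082, 0.101 or 0.0733 without wild-type replicates 1, 2 or 3, 0.0547 without Δvps13 replicate 2 and 0.0616 in the 2 groups alone. The gene of the cellulase and xylanase activator Xyr1, xyr1, had 1741 ± 872 CPM against 947 ± 62.3 and was not called (log2 0.88, SE 0.36, adjusted p = 0.135, and 0.00489 without Δvps13 replicate 1 or 0.00124 with sample quality weights). The carbon catabolite repressor gene cre1 was not called either (log2 0.36, adjusted p = 0.469, and 0.0425 without Δvps13 replicate 1 or 0.0247 with sample quality weights).

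In all, 3 gene lists shifted as sets in Δvps13 (limma camera, Benjamini-Hochberg over 22 lists), and each call was lost when the correlation between genes was estimated from the data. Of 13 tested cellulases and cellulose-active proteins, 8 rose, 2 fell and 3 were not called (9 up and 2 down when adjusted over the list alone), with a median log2 of 1.58 (adjusted p = 8.26e-04, and adjusted p = 0.719 with an estimated correlation). The 2 that fell were the GH12 gene TRIREDRAFT_77284 (log2 -1.14) and TRIREDRAFT_123946, described as a dehydrogenase associated with cellulase signal transduction, which was 4.77-fold lower (adjusted p = 0.00113). Without wild-type replicates 1, 2 or 3 the list held 4, 3 or 4 increases and 1 decrease. Of 13 genes of ER entry, folding and glycosylation, 2 rose (7 adjusted over the list alone), with a median log2 of 0.54 (adjusted p = 0.00164, and adjusted p = 0.174 with an estimated correlation), and 6 rose without Δvps13 replicate 1 or without replicate 3. Of 49 cytosolic ribosomal protein genes, 3 fell (3 adjusted over the list alone), with a median log2 of -0.54 (adjusted p = 4.91e-10, and adjusted p = 0.719 with an estimated correlation). Among them a gene of ribosomal protein L41 (NW_006711167.1, 213797 to 214514) was 4.09-fold lower, at 329 ± 137 CPM against 1347 ± 408 (adjusted p = 0.00728). The ribosomal count moved with Δvps13 replicate 3: 36 genes fell when that library was left out, and 1 fell without wild-type replicate 1, 2 or 3 or without Δvps13 replicate 2. By DESeq2 15 of the 49 fell, and 40 did when scaled by library totals only. The alternative test fry asks whether the genes of a list changed, without setting them against other genes. It called the ER and ribosomal lists in Δvps13 (adjusted p = 3.64e-04 and 0.0459) but not the cellulases (adjusted p = 0.0574).

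With all libraries no other list of 5 or more tested genes shifted as a set in Δvps13. Leaving out 1 library added heat shock genes upward (without Δvps13 replicate 1, adjusted p = 0.00287) or vesicle transport genes upward (without Δvps13 replicate 3, adjusted p = 0.0255). Where the count adjusted over the list alone differed from that over all genes, it is given as "alone". Among wall-active enzymes, 1 of 13 beta-glucosidases rose, 3 of 21 hemicellulases rose and 3 fell, and of 48 enzymes of chitin and beta-1,3-glucan 3 rose and 4 fell (alone 3 and 5). That list had a median of -0.067 and a mean of 0.003, with a downward test. In membrane traffic, 5 of 74 vesicle transport genes rose and 1 fell (none alone), whereas of 18 endosome and vacuolar sorting genes 0 were called (at unadjusted p below 0.05, 1 higher and 3 lower, and 1 lower by DESeq2). The single autophagy gene was not called. Of 36 proteases and peptidases 3 fell (alone 6), and of 10 proteasome genes 0 were called (2 lower at unadjusted p below 0.05, 0 by DESeq2). Of 6 heat shock and chaperone genes 1 rose, and of 5 genes of mitochondrial respiration 0 were called (0 at unadjusted p below 0.05 and 0 by DESeq2). In uptake, 2 of 11 sugar transporters rose and 1 fell, 4 of 32 genes of nitrogen and amino acid uptake rose and 2 fell, and 1 of 7 iron uptake genes, TRIREDRAFT_111750, fell. The iron list had a median of 0.33, a mean of -0.098 and a downward test.

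In metabolism, 7 of 28 genes of glycolysis and the citric acid cycle rose and 2 fell (alone 7 and 4), and of 35 genes of lipid metabolism and transfer 4 rose and 2 fell (alone 7 and 3). Of 17 genes of secondary metabolism and cytochrome P450 3 rose and 1 fell (alone 4 and 1), and of 19 redox defence genes 2 fell, among them TRIREDRAFT_66345. In development and regulation, 2 of 6 conidiation and hydrophobin genes rose (alone 3 up and 1 down), 2 of 4 mating genes fell (alone 3; too few for the list test, which with a 5th gene gave an adjusted p of 0.0411 downward without wild-type replicate 2), 2 of 47 transcription factor genes rose and 2 fell (alone 3 and 2), and 2 of 42 genes of cell cycle, replication and cytoskeleton fell. None of the 4 ABC and drug transporter genes was called. The lists for the vacuolar proton pump and for ribosome biogenesis matched no gene description. With 1 library left out, the counts over all genes ranged as follows, with decreases of a count reaching their lowest without a wild-type library and increases their highest without Δvps13 replicate 1 or 3. In wall-active enzymes and transporters these were beta-glucosidases 0 to 3 up and 0 to 2 down, hemicellulases 1 to 5 up and 0 to 5 down, enzymes of chitin and beta-1,3-glucan 0 to 7 up and 1 to 10 down, sugar transporters 1 to 3 up and 0 to 4 down, nitrogen and amino acid uptake 2 to 14 up and 0 to 6 down, iron uptake 0 to 1 up, and ABC transporters 0 to 2 up. In traffic and degradation they were endosome and vacuolar sorting 0 to 2 up and 0 to 2 down, autophagy 0 to 1 up, vesicle transport 0 to 16 up and 0 to 4 down, proteases 0 to 8 up and 0 to 12 down, proteasome 0 to 2 down, and heat shock genes 0 to 3 up. In the rest they were glycolysis and citric acid cycle 1 to 10 up and 1 to 5 down, lipid metabolism 0 to 11 up and 0 to 4 down, secondary metabolism 0 to 7 up and 0 to 1 down, redox defence 0 to 1 up and 1 to 7 down, conidiation 0 to 3 up and 0 to 1 down, mating 1 to 3 down, transcription factors 0 to 8 up and 0 to 3 down, and cell cycle 0 to 4 up and 0 to 4 down. Over all lists together 79 members were called in Δvps13 (46 up, 33 down). Leaving out wild-type replicates 1, 2 or 3 gave 27, 19 or 22, leaving out Δvps13 replicates 2 or 3 gave 43 or 226, and leaving out Δvps21 replicates 1, 2 or 3 gave 54, 57 or 54, with 102 without Δvps13 replicate 1.

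In total 926 genes were called in Δvps13, 503 up and 423 down. Scaled by library totals only, with a median shift of -0.301 in log2, the split was 173 up and 1089 down. The total was 282, 165 or 256 without wild-type replicates 1, 2 or 3, 491 without Δvps13 replicate 2, 3233 without Δvps13 replicate 3, and 583 without Δvps21 replicate 3.

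The comparison of Δvps21 with the wild type asks which transcripts differ when vps21 is deleted. Several cellulase genes rose. The cellobiohydrolase gene cel7a rose 4.34-fold, from 10311 ± 1335 to 44717 ± 4494 CPM (n = 3 per group, log2 2.12, SE 0.42, adjusted p = 0.00358), and the GH6 gene TRIREDRAFT_72567 rose 6.77-fold, from 5693 ± 778 to 38523 ± 5397 CPM (log2 2.76, SE 0.46, adjusted p = 0.00147). The endoglucanase gene cel7b (NW_006711157.1, 665665 to 667273) rose 5.28-fold, from 386 ± 66.7 to 2037 ± 315 CPM (log2 2.40, SE 0.38, adjusted p = 0.00112). Increases of 6.88-fold for cip2, 4.45-fold for the beta-glucosidase gene cel3a and 2.86-fold for the GH10 gene TRIREDRAFT_120229 were also called (adjusted p = 4.00e-04, 0.00352 and 0.00154). The ER chaperone gene bip1 (NW_006711163.1, 512482 to 515161) rose 3.78-fold, from 561 ± 27.1 to 2121 ± 382 CPM (log2 1.92, SE 0.28, adjusted p = 6.19e-04). The gene pdi1 (NW_006711159.1, 434677 to 436583) rose 3.10-fold, from 326 ± 41.7 to 1010 ± 144 CPM (log2 1.63, SE 0.24, adjusted p = 6.36e-04), and the calnexin gene TRIREDRAFT_73678 rose 1.80-fold (adjusted p = 0.00731).

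Among the largest increases in Δvps21 were genes with low expression in the wild type. TRIREDRAFT_112258, described only as a predicted protein, went from 0.154 ± 0.141 to 120.3 ± 10.98 CPM (adjusted p = 2.78e-04). A multicopper oxidase gene, TRIREDRAFT_124079, went from 0.4 ± 0.257 to 194 ± 4.33 CPM (log2 8.85, SE 1.12, adjusted p = 3.12e-04, and log2 9.54 without wild-type replicate 1), ooc1 from 4.90 ± 0.518 to 794 ± 102 (log2 7.34, SE 1.04, adjusted p = 5.73e-04), and the class II hydrophobin gene TRIREDRAFT_106538 from 7.09 ± 0.708 to 1091 ± 108 (log2 7.26, SE 1.08, adjusted p = 7.72e-04). A galactose permease gene, TRIREDRAFT_106556 (NW_006711154.1, 999132 to 1000966), went from 1.69 ± 0.698 to 244 ± 43.7 CPM (log2 7.18, SE 0.46, adjusted p = 6.68e-06). An amino acid transporter gene, TRIREDRAFT_121486, rose 113-fold (adjusted p = 1.42e-04) and a proteinase inhibitor gene, TRIREDRAFT_72379, 63.7-fold (adjusted p = 7.41e-04). Among decreases, an alcohol oxidase gene, TRIREDRAFT_123978, was 13.2-fold lower, at 11.4 ± 2.31 CPM against 151 ± 20.2 (log2 -3.72, SE 0.35, adjusted p = 8.76e-05). The gene min1 was 12.5-fold lower, the hexose transporter gene hxt1 10.01-fold lower, and the chitinase gene chi18-2 8.38-fold lower (adjusted p = 2.58e-04, 0.00112 and 0.00226). The glycolytic gene pgk1, for phosphoglycerate kinase, was 3.73-fold lower, at 1423 ± 131 CPM against 5314 ± 1291 (adjusted p = 0.00637).

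**Figure D2:**
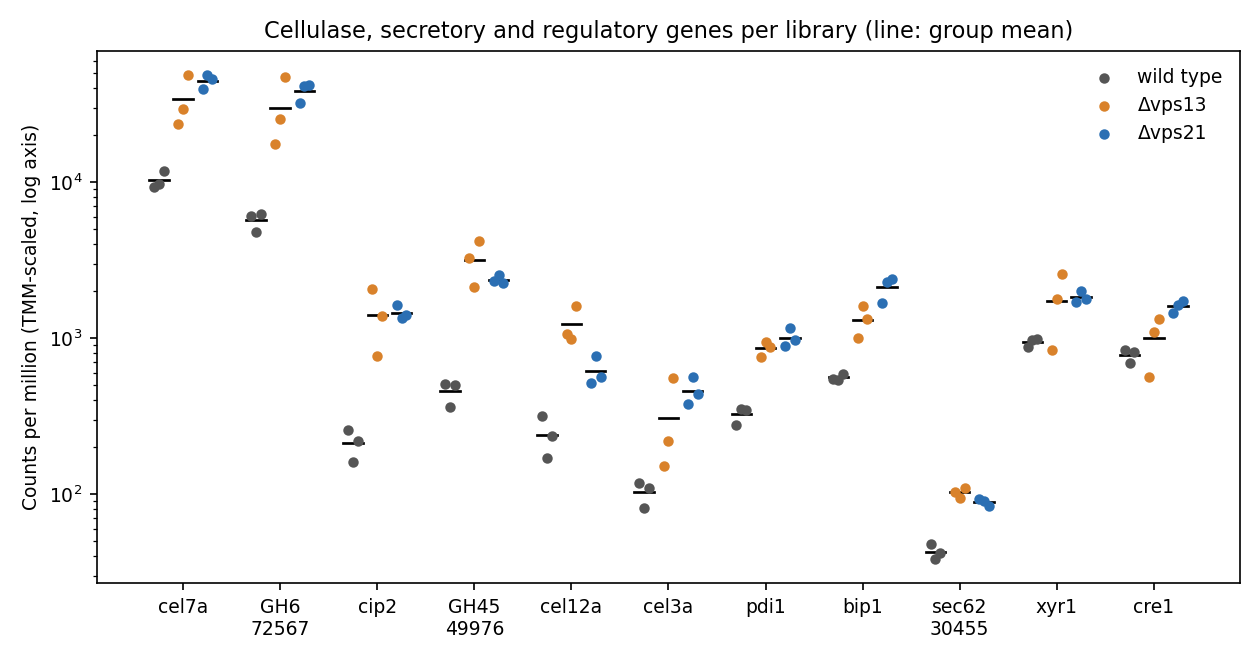
CPM on a log axis for 11 cellulase, secretory and regulatory genes; each point is 1 library, coloured by strain, and each line is the mean of 3 libraries. The cel7a mean is 10311 CPM in the wild type, 33956 in Δvps13 and 44717 in Δvps21, and the xyr1 means are 947, 1741 and 1833.

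Of the regulators of these enzymes, cre1 rose 2.06-fold in Δvps21, from 778 ± 77.8 to 1603 ± 142 CPM (log2 1.04, SE 0.31, adjusted p = 0.0256). That call was lost in 6 fits that left out 1 library: the adjusted p was 0.0648, 0.106 or 0.0685 without wild-type replicates 1, 2 or 3 and 0.0521, 0.0622 or 0.0863 without Δvps21 replicates 1, 2 or 3. The allele carried by Rut-C30 is a truncated one, so this concerns the transcript only. The activator gene xyr1 had 1833 ± 156 CPM against 947 ± 62.3 and was not called (log2 0.95, SE 0.36, adjusted p = 0.0628). It was called without Δvps13 replicates 1 or 3 (adjusted p = 0.00201 and 0.0121), by DESeq2 (adjusted p = 0.0192), with scaling by library totals only (adjusted p = 0.0214), in a fit of the 2 groups alone (adjusted p = 8.57e-05), with a replicate block (adjusted p = 0.0493) and with sample quality weights (adjusted p = 1.84e-04). The stress sensor gene ire1 was not called (log2 0.29, adjusted p = 0.29, and 0.0456 with sample quality weights), nor was the beta-glucosidase gene cel1a (log2 0.22, adjusted p = 0.692).

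Likewise 3 lists shifted as sets in Δvps21, and these calls too were lost with an estimated correlation. Of 13 cellulases and cellulose-active proteins 10 rose and 1 fell (the same adjusted over the list alone), with a median log2 of 1.86 (adjusted p = 0.00143, and adjusted p = 0.644 with an estimated correlation). The 1 that fell was again the dehydrogenase gene TRIREDRAFT_123946, 8.86-fold lower (adjusted p = 3.04e-05). Of 49 cytosolic ribosomal protein genes 26 fell (32 adjusted over the list alone, 34 by DESeq2), with a median log2 of -0.63 (adjusted p = 3.15e-08, and adjusted p = 0.644 with an estimated correlation). The L41 gene was 4.03-fold lower (adjusted p = 0.00164). The ribosomal count was 10, 8 or 11 without wild-type replicates 1, 2 or 3 and 5, 11 or 5 without Δvps21 replicates 1, 2 or 3. Of 6 heat shock and chaperone genes 4 rose (6 adjusted over the list alone), with a median log2 of 1.13 (adjusted p = 0.00988, and adjusted p = 0.644 with an estimated correlation), and 2 rose without wild-type replicate 1 or without Δvps21 replicate 3. Its members TRIREDRAFT_35465, an ER heat shock protein gene, and TRIREDRAFT_119731, for Hsp60, rose 3.42-fold and 3.25-fold (adjusted p = 4.04e-04 and 0.00152). The cellulase, ribosomal and heat shock lists were also called by fry (adjusted p = 0.0107, 0.0095 and 0.00713).

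Other wall-active enzymes moved both ways in Δvps21. Of 13 beta-glucosidases 4 rose, among them the GH3 gene TRIREDRAFT_47268, 6.37-fold (adjusted p = 4.47e-04), and 1 fell. Of 21 hemicellulases 5 rose and 8 fell (alone 6 and 8), with a median of 0.46, a mean of -0.18 and a downward test. In that list the GH54 gene TRIREDRAFT_55319 rose 6.10-fold and the GH36 gene TRIREDRAFT_64827 was 6.74-fold lower (adjusted p = 0.00211 and 2.66e-04). Of 48 enzymes of chitin and beta-1,3-glucan 14 rose and 10 fell (alone 16 and 10), including increases of the GH18 gene TRIREDRAFT_112392, 35.7-fold, and the GH81 gene TRIREDRAFT_79602, 11.3-fold (adjusted p = 1.80e-04 and 2.43e-04). Of 11 sugar transporters 4 rose and 1 fell (alone 4 and 2), with a second galactose permease gene, TRIREDRAFT_62380, 14.3-fold higher and the sugar transporter gene TRIREDRAFT_69026 8.95-fold higher (adjusted p = 1.13e-04 and 3.24e-05). The decrease was hxt1. Of 32 genes of nitrogen and amino acid uptake 9 rose and 3 fell, and of 4 ABC and drug transporter genes 2 rose, among them TRIREDRAFT_123293, 3.32-fold (adjusted p = 0.00262).

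In the secretory and degradative pathways of Δvps21, 4 of 13 genes of ER entry, folding and glycosylation rose and 1 fell (alone 4 and 2). The decrease was TRIREDRAFT_5350, for the beta subunit of the signal recognition particle receptor, 3.13-fold lower (adjusted p = 0.00107). Of 74 vesicle transport genes 10 rose and 5 fell, with a median of -0.002, a mean of 0.104 and an upward test. The rab GTPase gene TRIREDRAFT_63053 rose 5.58-fold, the syntaxin gene TRIREDRAFT_3340 2.61-fold and the Golgi sorting nexin gene TRIREDRAFT_106014 2.51-fold (adjusted p = 3.54e-04, 0.00104 and 0.00217). Of 18 endosome and vacuolar sorting genes 2 rose and 3 fell, with a median of 0.105, a mean of -0.405 and a downward test, and 1 of the decreases was the missing rab5-like gene itself. The only autophagy gene tested, the protease gene TRIREDRAFT_48351, rose 1.74-fold (adjusted p = 0.0103, and 0.161 with scaling by library totals only). Of 36 proteases and peptidases 8 rose and 7 fell (alone 8 and 8), with the M18 peptidase gene TRIREDRAFT_47127 6.24-fold higher and a serine protease gene, TRIREDRAFT_58698, 3.15-fold lower (adjusted p = 2.70e-04 and 0.00149). Of 10 proteasome genes 0 were called (0 at unadjusted p below 0.05 and 0 by DESeq2).

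In metabolism, 9 of 28 genes of glycolysis and the citric acid cycle rose and 5 fell in Δvps21 (alone 12 and 5). The hexokinase gene TRIREDRAFT_79677 rose 4.52-fold and the aconitase gene TRIREDRAFT_77336 3.31-fold (adjusted p = 1.91e-04 and 0.00759), while pgk1 fell. Of 35 genes of lipid metabolism and transfer 6 rose and 8 fell, with a lysophospholipase gene, TRIREDRAFT_70527, 8.89-fold higher, a lanosterol demethylase gene, TRIREDRAFT_75468, 3.82-fold lower and a phospholipase D gene, TRIREDRAFT_78611, 3.69-fold lower (adjusted p = 1.59e-04, 0.00322 and 0.00377). Of 19 redox defence genes 3 rose and 4 fell (alone 3 and 5), and the glutathione transferase gene TRIREDRAFT_41895 was 6.46-fold lower (adjusted p = 2.58e-04). Of 7 iron uptake genes 1 rose and 2 fell (alone 1 and 3). Of 5 genes of mitochondrial respiration 1 fell, with a median of 0.048, a mean of -0.142 and a downward test. Of 17 genes of secondary metabolism and cytochrome P450 1 rose and 2 fell. In development and regulation, 1 of 6 conidiation and hydrophobin genes rose (alone 4), which was TRIREDRAFT_106538. That list was not called by camera with all libraries, but shifted upward by fry (adjusted p = 0.032) and by camera without Δvps13 replicate 2 (adjusted p = 0.0401). In addition 1 of 4 mating genes fell, the pheromone receptor gene TRIREDRAFT_64018 (adjusted p = 0.00376). Of 47 transcription factor genes 5 rose and 5 fell (alone 5 and 3). Of 42 genes of cell cycle, replication and cytoskeleton 11 rose and 5 fell, with a tubulin alpha gene, TRIREDRAFT_120830, 4.90-fold higher and a kinesin gene, TRIREDRAFT_66486, 4.49-fold lower (adjusted p = 8.23e-04 and 0.0015).

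**Figure D3:**
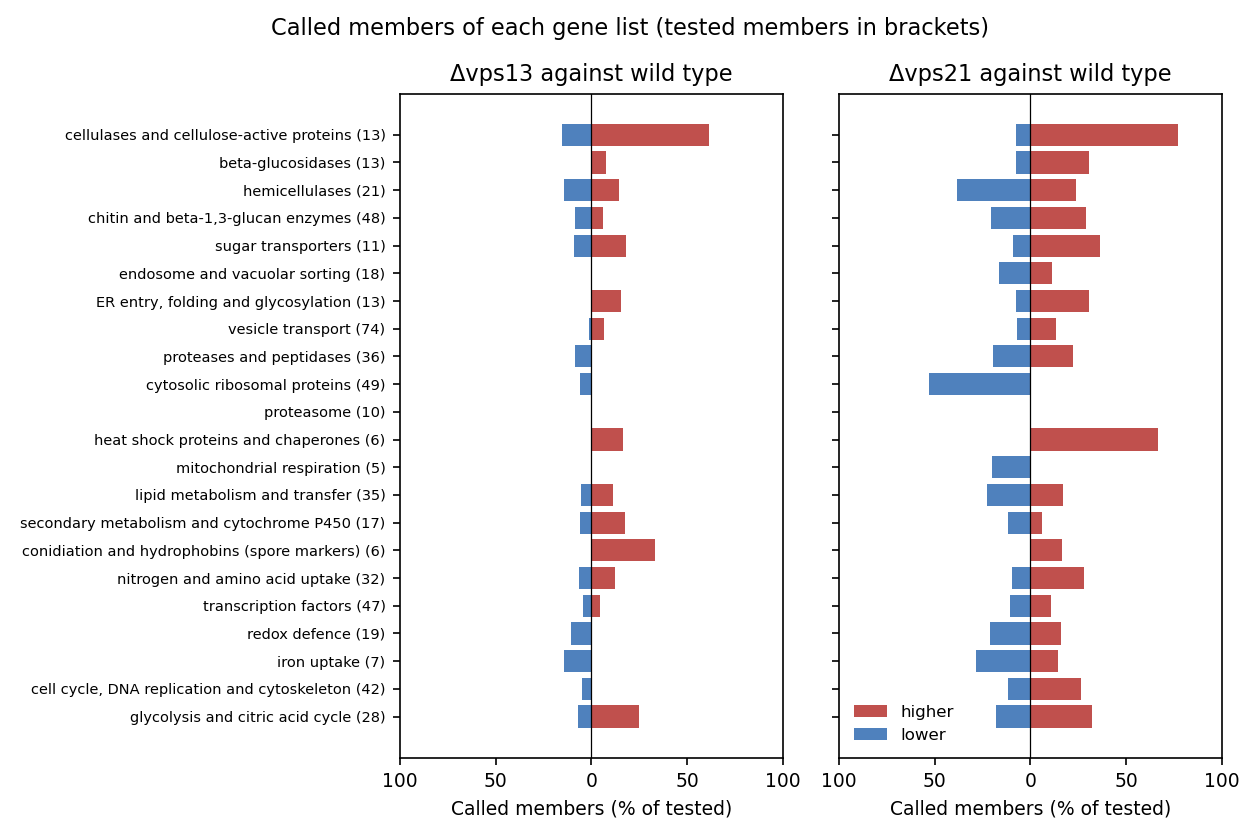
Share of the tested members of each gene list that was called higher (red, to the right) or lower (blue, to the left) in Δvps13 and in Δvps21 against the wild type, in percent of tested members, whose number stands in brackets. Cellulases have 8 and 10 increases of 13, and ribosomal proteins 3 and 26 decreases of 49.

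In total 2897 genes were called in Δvps21, 1489 up and 1408 down. Scaled by library totals only, with a median shift of -0.181 in log2, the split was 872 up and 1678 down. The total was 1810 without wild-type replicate 2 and 1901 or 1705 without Δvps21 replicates 1 or 3. Over all lists together 211 members were called (112 up, 99 down), and 144 without Δvps21 replicate 3. Of the lists above, with 1 library left out, counts ranged over 0 to 1 down in beta-glucosidases, 3 to 10 up in hemicellulases, 9 to 18 up in enzymes of chitin and beta-1,3-glucan, 1 to 2 down in sugar transporters, 1 to 2 up and 1 to 4 down in endosome and vacuolar sorting, 1 to 2 down in the ER list, 1 to 11 down in vesicle transport and 5 to 10 up in proteases. They ranged over 5 to 15 up in glycolysis and citric acid cycle, 2 to 5 up in redox defence, 1 to 3 down in iron uptake, 0 to 1 down in mitochondrial respiration, 0 to 2 up and 1 to 4 down in secondary metabolism, 1 to 4 up in conidiation, 2 to 11 up and 2 to 9 down in transcription factors, 1 to 3 up in ABC transporters, and 7 to 17 up and 2 to 7 down in cell cycle genes. The highest of these came without Δvps13 replicate 3 and the lowest without a wild-type or Δvps21 library. Apart from cre1, each gene named for this comparison with a call kept it when any 1 library was left out.

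Compared directly, the 2 deletion strains differed in single genes for transporters, a hexokinase, chitinases and a protease, while cel7a and the GH6 gene were not called. The lactate/pyruvate transporter gene TRIREDRAFT_121441, higher than wild type in Δvps13 and lower in Δvps21, was 74.5-fold lower in Δvps21 than in Δvps13, at 3.26 ± 0.692 CPM against 243 ± 111 (n = 3 per group, log2 -6.22, SE 0.37, adjusted p = 8.57e-06). The hexokinase gene TRIREDRAFT_79677 was 16.1-fold higher, at 1324 ± 91.2 CPM against 82.5 ± 22.3 (SE 0.27, adjusted p = 1.68e-05). The galactose permease gene TRIREDRAFT_106556 was 25.8-fold higher, at 244 ± 43.7 CPM against 9.44 ± 5.29 (log2 4.69, SE 0.40, adjusted p = 8.97e-05). The amino acid transporter gene TRIREDRAFT_121486 was 34.5-fold higher (adjusted p = 8.15e-04, and 59.1-fold without Δvps13 replicate 2), an amidase gene, TRIREDRAFT_109378, 12.6-fold higher (adjusted p = 1.21e-04), and the chitinase gene chi18-5 14.1-fold higher (adjusted p = 4.18e-04). In the other direction, chi18-2 was 7.95-fold lower, the L-xylulose reductase gene lxr1 7.02-fold lower, the glutathione transferase gene TRIREDRAFT_41895 6.94-fold lower and the serine protease gene TRIREDRAFT_58698 4.72-fold lower (adjusted p = 0.00583, 0.00302, 5.35e-04 and 7.45e-04). Without Δvps13 replicate 3, chi18-2 was 4.10-fold lower and lxr1 4.06-fold lower. Each of these calls was kept when any 1 library was left out.

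Several of the cellulase, secretory and regulatory genes named above were not called between the deletion strains. Between Δvps21 and Δvps13 the log2 ratio was 0.40 for cel7a (adjusted p = 0.554), 0.36 for TRIREDRAFT_72567 (adjusted p = 0.622), 0.23 for pdi1 (adjusted p = 0.549) and 0.07 for xyr1 (adjusted p = 0.913). With scaling by library totals only, cel7a was called (adjusted p = 0.0449). The log2 ratio of bip1 was 0.70 (adjusted p = 0.102), and it was called by DESeq2 (adjusted p = 0.0246) and with library totals (adjusted p = 0.0175). That of cre1 was 0.69 (adjusted p = 0.163, and 0.0377 without Δvps13 replicate 3, 0.0117 with library totals and 0.0237 with sample quality weights).

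By camera no gene list shifted as a set between the deletion strains, the lowest adjusted p among 22 lists being 0.174. Without Δvps13 replicate 3, beta-glucosidases and sugar transporters shifted upward by camera and secondary metabolism downward (adjusted p = 0.0147, 0.0294 and 0.0147). By fry 8 lists were called with all libraries. Chitin and beta-1,3-glucan enzymes, sugar transporters and cell cycle genes were upward. Endosome and vacuolar sorting, ER, mitochondrial respiration, lipid metabolism and secondary metabolism were downward. The 1 called decrease in the endosome list was the missing rab5-like gene TRIREDRAFT_123015 itself (log2 -9.49). The downward fry call of that list is therefore no result about the other endosome genes. Of the cellulases 1 was higher in Δvps21 and 1 lower (alone 1 and 2). In the beta-glucosidase list 2 were higher (alone 3), TRIREDRAFT_47268 (3.31-fold, adjusted p = 0.00866) and TRIREDRAFT_79669 (2.51-fold, adjusted p = 0.0038). The latter is described only as a GH3 gene. Of hemicellulases 1 was higher, TRIREDRAFT_55319 (7.09-fold, adjusted p = 0.0038, and 14.5-fold without Δvps13 replicate 2), and 4 lower (alone 2 and 6). Enzymes of chitin and beta-1,3-glucan had 11 higher and 6 lower (alone 14 and 9). Sugar transporters had 3 higher, TRIREDRAFT_106556, TRIREDRAFT_62380 (9.57-fold, adjusted p = 5.13e-04) and TRIREDRAFT_69026 (9.21-fold, adjusted p = 7.67e-05), with a median of -0.056, a mean of 0.873 and an upward test. Proteases and peptidases had 7 higher and 4 lower (alone 8 and 4; median -0.024, mean 0.248), among the former an aspartic peptidase gene, TRIREDRAFT_121133 (4.28-fold, adjusted p = 2.33e-04), and TRIREDRAFT_47127 (4.04-fold, adjusted p = 0.00248). In membrane traffic, vesicle transport had 3 higher and 2 lower (alone 1 higher), the endosome list 1 higher and 1 lower (median -0.032, mean -0.425, upward test), and the ER list 1 lower, TRIREDRAFT_5350 (3.02-fold lower, adjusted p = 0.00309). The autophagy gene was not called. Of the ribosomal protein genes 0 were called (0 at unadjusted p below 0.05 and 0 by DESeq2), and of the proteasome genes also 0 (6 higher at unadjusted p below 0.05, 0 by DESeq2).

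Among the remaining lists of the direct comparison, heat shock and chaperone genes had 1 higher, TRIREDRAFT_119731 (2.74-fold, adjusted p = 0.00783; alone 2), mitochondrial respiration 1 lower, lipid metabolism 3 higher and 5 lower (alone 6 and 8), and secondary metabolism 3 lower. Conidiation and hydrophobins had 1 higher (alone 2), mating genes 1 higher (alone 3), which was the mating type gene mata1 at 10.96 ± 0.951 CPM against 4.34 ± 0.415 (adjusted p = 0.0046), and nitrogen and amino acid uptake 3 higher and 2 lower. Transcription factors had 1 higher and 3 lower (alone 1 lower; median 0.020, mean -0.009, downward test), redox defence 3 higher and 1 lower (alone 5 and 3), iron uptake 1 higher and 2 lower (alone 2 and 2) and ABC transporters 1 higher, TRIREDRAFT_123293 (3.75-fold, adjusted p = 0.00393). Cell cycle, replication and cytoskeleton had 11 higher and 4 lower (alone 11 and 5), with a tubulin beta gene, TRIREDRAFT_21742, 2.53-fold higher (adjusted p = 0.00114), and glycolysis and the citric acid cycle 3 higher and 3 lower (alone 4 and 3). With 1 library left out, counts ranged over 0 to 4 higher and 0 to 2 lower in cellulases, 2 to 5 and 0 to 3 in beta-glucosidases, 1 to 6 and 0 to 7 in hemicellulases, 8 to 15 and 3 to 8 in enzymes of chitin and beta-1,3-glucan, 3 to 6 and 0 to 1 in sugar transporters, 1 to 5 and 0 to 11 in vesicle transport, and 2 to 8 and 1 to 6 in proteases. In the same order they ranged over 2 to 6 and 2 to 7 in lipid metabolism, 2 to 4 and 1 to 4 in nitrogen uptake, 0 to 4 and 1 to 4 in transcription factors, 1 to 5 and 1 to 3 in redox defence, 1 to 2 and 0 to 3 in iron uptake, 3 to 12 and 2 to 8 in cell cycle genes, and 1 to 6 and 0 to 5 in glycolysis and citric acid cycle. One direction moved in endosome and vacuolar sorting (0 to 1 higher), proteasome (0 to 5 higher), conidiation (0 to 3 higher), mating (1 to 2 higher), ER (1 to 2 lower), mitochondrial respiration (0 to 1 lower) and secondary metabolism (0 to 6 lower). The highest of these came without a Δvps13 library and the lowest without a Δvps21 library. Over all lists 100 members were called (57 higher, 43 lower), with 158 without Δvps13 replicate 3 and 50, 53 or 43 without Δvps21 replicates 1, 2 or 3. In total 1356 genes differed, 684 higher and 672 lower in Δvps21. Scaled by library totals only, with a median shift of 0.118, the split was 691 and 395. The total was 2216 without Δvps13 replicate 3 and 744, 770 or 514 without Δvps21 replicates 1, 2 or 3.

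Some of the strongest differences between the deletion strains lay side by side on 1 scaffold, NW_006711161.1. The carbohydrate esterase family 9 gene TRIREDRAFT_79671 (714385 to 716448) had 667 CPM in the wild type, 154 in Δvps13 and 2630 in Δvps21, and was 17.1-fold higher in Δvps21 than in Δvps13 (adjusted p = 8.05e-04, and 33.4-fold without Δvps13 replicate 2). Enzymes of this family remove acetyl groups from N-acetylglucosamine phosphate. TRIREDRAFT_49898 (721359 to 723042), picked after the data were seen, had 553, 90.8 and 2742 CPM (adjusted p = 5.33e-04 between the deletion strains). Its values in Δvps13 replicates 1, 2 and 3 were 73.0, 170.7 and 28.7 CPM. The hexokinase gene TRIREDRAFT_79677 (728079 to 729984) had 293, 82.5 and 1324 CPM, and the GH3 gene TRIREDRAFT_79669 (708757 to 712529) 143, 107 and 269 CPM. Between them, TRIREDRAFT_79673 (718618 to 720808), also picked after the data were seen, had 106, 121 and 232 CPM.

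**Figure D4:**
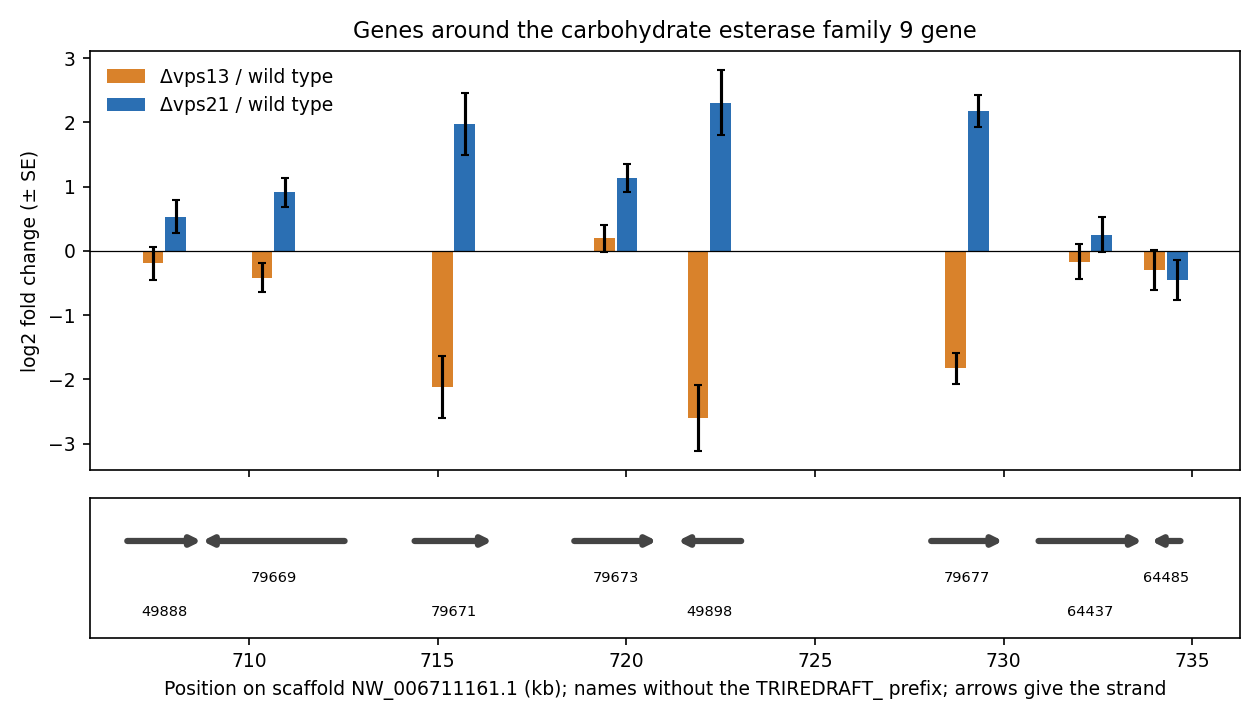
Log2 change against the wild type (bars, with SE as error bars) of genes around the carbohydrate esterase gene TRIREDRAFT_79671 in Δvps13 and Δvps21, n = 3 libraries per group, against position on the scaffold in kb; arrows give gene extent and strand. The hexokinase gene TRIREDRAFT_79677 stands at 82.5 CPM in Δvps13 and 1324 in Δvps21.

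The changes in the 2 deletion strains overlapped in direction. Of the genes called in both, 624 changed in the same direction, 320 up and 304 down, where independent calls would give 84.1 up and 66.9 down, and 17 changed in opposite directions, where independent calls would give 150. Both comparisons use the same 3 wild-type libraries, which alone pull the changes into the same direction. In 20 simulations with shared wild-type libraries and no response in either strain, 91.6 genes on average had the same direction and 1.25 opposite directions at unadjusted p below 0.05, against 1608 and 78 observed. Because no strain responds in these simulations, the counts do not show how far independent responses that share the wild type would overlap. The covariance of the log2 changes was 0.656 against 0.0747 in the simulations, their correlation 0.656 against 0.493, and the share of genes with the same sign 74.3% against 66.5%. The simulations gave all groups the same spread, whereas the median SD was 0.191 in the wild type, 0.501 in Δvps13 and 0.228 in Δvps21. The simulated values are therefore not an exact baseline for these libraries. The opposite count was 3, 2 or 3 without wild-type replicates 1, 2 or 3, 49 or 64 without Δvps13 replicates 1 or 3, and 9, 9 or 8 without Δvps21 replicates 1, 2 or 3. The same-direction count was 216, 132 or 189 without wild-type replicates 1, 2 or 3, 329 or 2050 without Δvps13 replicates 2 or 3, and 373 or 346 without Δvps21 replicates 1 or 3. By function, 8 cellulase genes rose in both strains, 3 hemicellulase genes rose and 3 fell in both, and 48 of 49 ribosomal protein genes had a negative log2 in both. Single genes that changed alike and kept both calls when any library was left out included cip2, pdi1, TRIREDRAFT_30455, TRIREDRAFT_120229, TRIREDRAFT_124002 and the amino acid transporter gene TRIREDRAFT_110813 upward, and min1, TRIREDRAFT_66345, TRIREDRAFT_111750, TRIREDRAFT_64018 and TRIREDRAFT_123946 downward. Of 2256 genes called only in Δvps21 (1351 without Δvps21 replicate 3), 866 also differed in the direct test (508, 551 or 371 without Δvps21 replicates 1, 2 or 3).

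**Figure D5:**
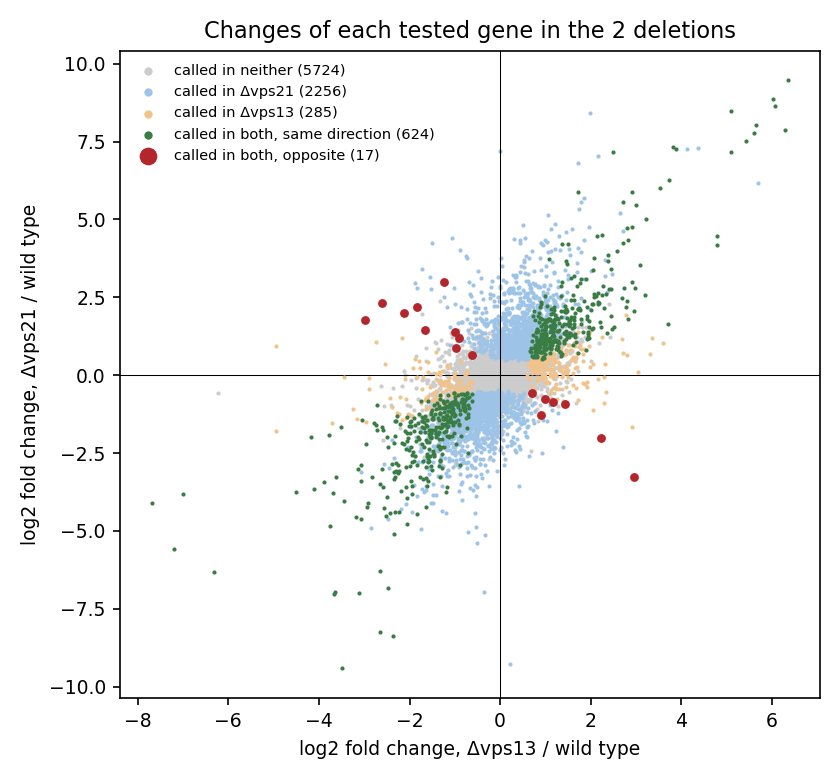
Log2 change in Δvps13 (horizontal) against log2 change in Δvps21 (vertical), both relative to the wild type; each point is 1 tested gene, coloured by where it was called. Called in both are 624 genes with the same direction and 17 with opposite directions.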

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

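The limma voom fit with sample quality weights was chosen only after the result was seen, and all other settings were chosen before. Its weights were 0.187, 2.73 and 0.171 for Δvps13 replicates 1, 2 and 3, so its Δvps13 means rest mostly on replicate 2. The number of called genes moved with the model and with the set of libraries, and 3 libraries per group leave each dispersion poorly known. The reported fit shares 1 estimate of spread per gene between the groups. The median SD was 0.191 in the wild type, 0.501 in Δvps13 and 0.228 in Δvps21. The wide Δvps13 spread therefore raises the estimate used for Δvps21, and the tighter groups lower the one used for Δvps13. No gene called both in the reported fit and in another setting changed direction between them.

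For Δvps13 against the wild type, 926 genes were called, 298 in a fit of the 2 groups alone, 1586 by DESeq2 and 4177 with voom quality weights; the cause was not tested. Leaving out 1 library gave 165 to 3233 genes. Fewer samples can be part of the cause of the lower counts, but not of the rise to 3233, which came without Δvps13 replicate 3. For Δvps21 against the wild type, 2897 genes were called, 4889 in a fit of the 2 groups alone and 5515 with voom quality weights; the cause was not tested. Leaving out 1 library gave 1705 to 4236. The highest came without Δvps13 replicate 3, which is in neither group compared and acts only through the shared fit. For Δvps21 against Δvps13, 1356 genes were called, 612 in a fit of the 2 groups alone and 3009 with voom quality weights; the cause was not tested. Leaving out 1 library gave 514 to 2216. The same-direction overlap of 624 genes ran from 132 to 2050 when 1 library was left out. Of the named genes with a call, 45 of 70, 19 of 91 and 24 of 59 in these comparisons lost it without some 1 library.

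With a replicate block the counts were 807, 2879 and 1289, with an overlap of 560, but same-numbered libraries did not pair: their residual correlations ran from -0.098 to 0.47, and other pairs from -0.427 to 0.419.

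With an estimated correlation, 0 lists were called in Δvps13 or in Δvps21, against 3 each with the preset value. By fry 2 lists were called in Δvps13, 7 in Δvps21 and 8 in Δvps21 against Δvps13, where camera called none. In Δvps21 fry added the sugar transporter, ER and conidiation lists upward (adjusted p = 0.00355, 0.00218 and 0.032). It added the endosome list, which holds the missing rab5-like gene, downward (adjusted p = 0.00218). Without Δvps13 replicate 3, camera called 3 lists in the direct comparison; the cause was not tested. Counted over all lists, comparisons and settings, 899 list results kept their call or lack of one, 18 gained a call and 7 lost it. Most of the 899 were lists without a call in the reported fit. The count therefore says little about how stable the 3 calls in each deletion strain were.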

Other observations

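The tests of a mislabelled library, of a mixture, of a few genes taking more of the counts and of other splits of the samples were chosen only after the result was seen. Of the 17 genes that changed in opposite directions in the 2 deletion strains, most have no informative description. Apart from TRIREDRAFT_121133, the genes in this paragraph and the next were picked after the data were seen. TRIREDRAFT_76682, a predicted protein, had 318 CPM in the wild type, 1484 ± 1050 in Δvps13 and 78.5 in Δvps21 (log2 2.22 and -2.02). Its values in Δvps13 replicates 1, 2 and 3 were 672, 2669 and 1112 CPM. A PTH11-type G-protein coupled receptor gene, TRIREDRAFT_76763, had log2 changes of 1.17 and -0.85, and TRIREDRAFT_124234, for an adenylate cyclase associated protein, -0.62 and 0.64. The aspartic peptidase gene TRIREDRAFT_121133 had -0.90 and 1.20.

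Next to the missing rab5-like gene, TRIREDRAFT_123014 (342497 to 345865) went from 69.0 CPM in the wild type to 249 in Δvps21 (log2 1.85, adjusted p = 1.07e-04), and on the other side TRIREDRAFT_27085 (348669 to 350596) went from 15.5 to 37.1 (log2 1.26, adjusted p = 0.00189). Other genes were close to absent in Δvps21: TRIREDRAFT_66776 went from 120 to 4.05 CPM (log2 -4.88, adjusted p = 3.04e-05) and TRIREDRAFT_105449 from 65.5 to 1.87 (log2 -5.13, adjusted p = 9.04e-06). A run of 29 adjacent annotated genes on NW_006711162.1 (247 to 85537) had 0 counts in all 9 libraries, and Rut-C30 is known to lack a large genomic segment of its ancestor.

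Δvps13 replicate 3 lay beside the wild type on the first principal component and apart from all other libraries on the third. Called between Δvps13 replicates 1 and 2 and the wild type, with each wild-type library left out in turn, were 1370, 1193 and 1341 genes. Of these, 70.07, 69.91 and 72.04% moved the same way in replicate 3. This argues against a mislabelled library that is like the other wild-type libraries. The share that a mislabelled library would show was assumed and not measured, and a wild-type culture in another state could share these changes. Mislabelling was therefore not excluded. A mixture of wild-type and Δvps13 material could neither be excluded nor shown, as 41 of 1355 abundant genes lay 2-fold or more beyond the range of the other 5 libraries (103 for Δvps13 replicate 1, 17 for replicate 2 and 0, 0 and 0 for the wild type). A gene length bias was excluded, because the mean correlation with the other Δvps13 libraries minus that with the wild type was -0.031 before and -0.0284 after the trend on length was removed. No biological explanation of the spread in Δvps13 was tested.

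Cytosolic ribosomal protein genes as a list were lower in Δvps21, a call that was lost with an estimated correlation (adjusted p = 0.644), and because these genes are short (median length 658 against 1373) an effect of RNA length may add to it. Among 10000 lists matched for length and abundance, 0.08% had a median in Δvps21 as low as -0.629, and their mean was -0.178. Genes of like length and abundance thus fell less on average. The matched genes were drawn 1 by 1 and lack the correlation between ribosomal protein genes, so their medians may vary too little. Length was therefore not excluded as the whole cause. Scaled by library totals only, the list lay at -0.62 from the median of all tested genes (-0.821 against -0.203). With TMM scaling the values were -0.629 against -0.022. Scaling moves all genes of a library alike, so this difference was nearly fixed beforehand. It is no separate test of whether a few genes took more of the counts. The lowest of 10000 random lists was -0.556, but random lists lack the correlation of 0.472 estimated between the ribosomal protein genes. These tests were run for Δvps21 only, and no biological explanation was tested.

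Adjacent genes changed together in Δvps21 more than in shuffled orders, with a correlation of 0.208 over 8853 pairs (highest shuffled value 0.0375). Reads running from 1 gene into the next might give this. Pairs at least 1 kb apart by the deposited coordinates still had 0.187 over 4513 pairs (highest shuffled value 0.0666). Reads shared between closer genes were therefore not the whole cause. Transcript ends were not analysed, so reads running 1 kb or further were not excluded. No biological explanation was tested.

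With 3 libraries against 3 there are 10 splits of each pair of groups, too few for a share below 0.05. The real split had 926, 2897 and 1356 called genes (2567, 3886 and 2712 at unadjusted p below 0.05), so 1 of 10 splits reached it each time. The highest other split had 0 in each (1305, 108 and 1385 at unadjusted p below 0.05).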
